A study of Mus musculus with 6 samples.

How the data were processed

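Bulk mRNA sequencing of 6 mouse samples was analysed, 3 titled control and 3 titled ethanol. The authors deposited 1 table of the whole series with a row per RefSeq transcript and, for each sample, a read count and an FPKM value, per the file headers. The submitters' processing notes name the mm10 build and bcl2fastq without versions, and the aligner and the counting tool are not given in the sources used here. The deposited read counts are estimated counts. In every library each checked count equalled the product of FPKM, transcript length and library size rounded up to a whole number, within 0.05 reads, for 100% of the 19603 to 23970 transcripts checked, while rounding to the nearest whole number fitted 49.1% to 50.0%. The deposited FPKM values were used for this check alone. Since the counts are estimates split among isoforms, reads of isoforms, paralogs and overlapping genes may be divided wrongly, and whether counting used strand was not stated. Rounding up adds up to 1 read per transcript.

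The 36780 transcripts were summed to 24532 genes by the gene identifier in the table, where 10 identifiers carried 2 symbols and were merged. The design fixed beforehand named the counts as deposited, so the summing is a departure that the unit required, and transcripts were also tested unsummed. No transcript of the mitochondrial genome was in the table used here. Coordinates are those of the table, 1-based, and the start equalled the RefSeq start for 15540 of 24462 matched genes.

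Genes were kept by filterByExpr of edgeR (minimum count 10), which left 15774. Libraries were scaled with TMM factors, and groups were compared by the quasi-likelihood test (glmQLFit and glmQLFTest) of edgeR 4.0.16 in R 4.3.3, with group as the only term. Tests were two-sided. Adjusted p-values are from Benjamini-Hochberg adjustment, with a threshold of 0.05. The standard error of a log2 fold change was taken as its size over the square root of the F statistic. CPM are counts per 1e6 reads of the TMM-scaled library, and mean ± SD are over the 3 samples of a group. The biological coefficient of variation was 0.252. Depth ranged from 35898026 to 67399599 estimated reads, so that 3 reads stood for 0.045 to 0.084 CPM, which covers counting error only.

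Of 39 gene lists written down before the data were examined, 37 were tested with camera (preset correlation 0.01) and adjusted over the 37. The list of mitochondrially encoded genes had 0 members in the table, and the sex-linked genes served as a check of the samples. Each list was also tested with an estimated correlation and with fry, and its members were adjusted over the list alone. Several genes stand in more than 1 list. Named genes followed a rule from before the data were examined. It took every gene past the threshold if there were at most 30, or else the 12 largest changes per direction. With fewer than 20 past the threshold it added the 8 genes per direction with the smallest unadjusted p and a mean log2 CPM of at least 1, unnamed gene models left out. It further took the 3 members of each list with the smallest unadjusted p together with members passing over the list alone, of which the text names at least those that passed. The checks Xist, Ddx3y, Fos, Bdnf, Drd1, Drd2, Ttr, Hbb-bs, Mbp and Slc17a7 were always named. The gene model Gm37013, which overlaps the Pcdha cluster and had the smallest p of all, was left out by this rule.

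DESeq2 1.42.0 and limma 3.58.1 (voom, with and without sample weights), other scalings and filters, a replicate block, thinned counts, other thresholds, and fits without each sample were alternatives chosen before the data were examined. Removal of GC and length trends, by a loess trend per library over GC content and log2 length of the longest GENCODE M21 transcript (97.1% of tested genes matched), was added after the data had been seen, as were the tests of single transcripts. The gene test was checked on 5 simulated sets of negative binomial counts with 200 changed genes each. Of genes changed 4-fold, 2-fold and 1.5-fold, edgeR called 94.1%, 40.9% and 2.5%. Among its calls 7.91% were false, against 24.0% for DESeq2 and 7.41% for limma-voom. The counts were drawn independently per gene from edgeR's own dispersion estimates. These rates may therefore favour edgeR, and they leave out differences between libraries that many genes share. The list test was checked on simulated lists of 15 genes and called 5 of 5 changed lists and 0 of 150 unchanged ones, with genes drawn independently. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.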

Results

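Messenger RNA from the nucleus accumbens core, a part of the ventral striatum that takes part in reward and motivated behaviour, was sequenced in 6 samples from male mice. The labels call the mice adolescent and give postnatal days 35 to 55, without saying to which step of the experiment that age applies. Per the labels, the mice went through contextual fear conditioning, 1 day of binge-like ethanol injections, extinction trials in the same context, and then 27 days of drinking with access every other day. Tissue was taken 24 h after the last drinking day. The ethanol schedule was 6 intraperitoneal injections of 20% v/v ethanol over 6 h, the first at 1.8 g/kg and the later ones at 1.2 g/kg. The sample titles gave 3 control and 3 ethanol samples. The treatment field of the labels read ethanol exposure in all 6 samples, so the groups rest on the titles, the sample descriptions and the column headers. What the control mice were injected with was not stated. The labels do not say that each sample came from a separate animal, so p-values measure the spread between these samples, which may be technical.

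The libraries held 55672232, 37215903 and 35898026 estimated reads in control 1, control 2 and control 3, and 67399599, 42995011 and 36197592 in ethanol 1, ethanol 2 and ethanol 3. Reads were found for 15924 genes in control 2 and for 17096 to 17707 genes in each of the other 5 libraries. Control 2 also stood apart on the first principal component of log2 CPM, which held 35.7% of the variance. The 10 most abundant genes took 3.76% to 4.57% of the reads of a library. No pair of libraries was alike within sampling noise, since the chi-square statistic per degree of freedom was at least 33.6 in every pair. Xist, the RNA of the inactive X chromosome, had 0 reads in all 6 libraries, where 3 reads would be 0.045 to 0.084 CPM. The Y-linked gene Ddx3y had 635 to 1501 reads in every library.

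The comparison of ethanol with control asked which transcripts differed between the groups in this tissue, taken after the drinking period. The labels give the 27 drinking days for control and ethanol samples alike, so drinking as such is not compared here. No single gene passed in edgeR, and the following 5 genes are among the 8 per direction that the rule for named genes took by unadjusted p. Cdh22, a cadherin of neuronal cell adhesion, stood at 20.96 ± 1.95 CPM in control and 47.9 ± 13.4 CPM in ethanol (SD, n = 3 each), a log2 fold change of 1.19 (SE 0.21). Cacng4, an auxiliary subunit of AMPA receptors, stood at 12.3 ± 1.02 and 24.6 ± 6.99 CPM, a log2 fold change of 1.004 (SE 0.22). Zwint, a kinetochore protein gene that is abundant in neurons, stood at 716 ± 107 and 1227 ± 170 CPM. Ap1g2, a subunit of a clathrin adaptor, stood lower, at 10.1 ± 1.75 CPM in control and 3.70 ± 1.05 CPM in ethanol, a log2 fold change of -1.45 (SE 0.27). Col16a1, a collagen chain, stood at 70.2 ± 18.4 and 31.5 ± 5.63 CPM, a log2 fold change of -1.16 (SE 0.22).

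The others of these 16 genes with higher values in ethanol were Pnmal1 (log2 fold change 1.46), Fam84a (0.85), Cables1 (0.73), Pcdha3 (3.23) and Pcdha11 (2.01). The 2 Pcdha genes encode clustered protocadherins, which share their last exons, so their estimated reads are uncertain. The others with lower values were Rps6kb2, a ribosomal S6 kinase (-1.16), Pnpla3, a lipid hydrolase (-1.18), P3h3, a collagen-modifying enzyme (-1.003), the long noncoding RNA Neat1 (-1.08), Clasrp, a splicing-related protein gene (-0.96), and Arhgef1, a guanine nucleotide exchange factor gene (-0.85). In all 16 genes the 3 ethanol libraries lay on 1 side of the 3 control libraries, which the choice of genes by p in this same comparison favours. In the mm10 build, Cdh22 lies on chromosome 2 from 165111507 to 165234737, Ap1g2 on chromosome 14 from 55098835 to 55106593, and Col16a1 on chromosome 4 from 130047840 to 130099277.

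**Figure D1:**
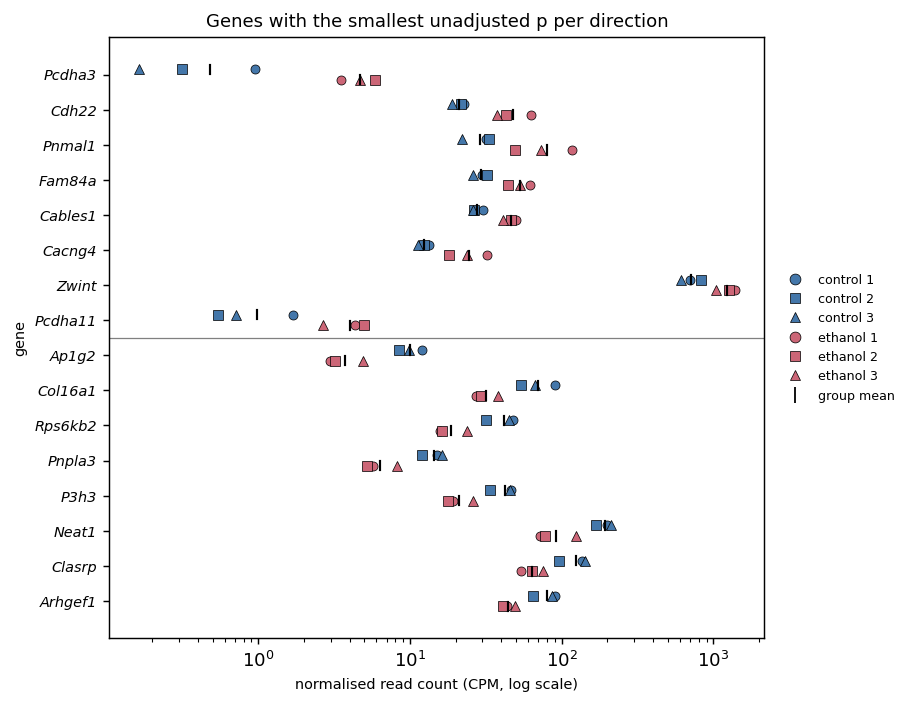
Normalised read count (CPM, log axis) of the 16 genes that the rule for named genes took by unadjusted p, 8 higher and 8 lower in ethanol. Each point is 1 library, and the black bars are group means. The control and ethanol points of each gene do not overlap, which the choice by p in these same libraries favours, and none of the 16 genes passed the adjusted test of edgeR.

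By edgeR's quasi-likelihood test, 0 genes were called higher and 0 lower of 15774 tested, and the smallest adjusted p was 0.41. At an unadjusted p under 0.05 there were 1681 genes, 838 higher and 843 lower in ethanol, where 789 would be met with no difference. limma-voom called 0 genes, with 1751 at an unadjusted p under 0.05, and DESeq2 called 51 genes higher and 93 lower. All 16 genes above were among them, which is no separate evidence since they were chosen from the same counts. Values of the 2 groups did not overlap in 1475 genes with ethanol above and 1326 with ethanol below, together 17.8% of the genes. Chance gives 10% on average, and the 789 genes are an average too. Other splits of the 6 samples into 3 and 3 gave from 51 to 1943 genes at an unadjusted p under 0.05. An excess over these averages is therefore no evidence of a group difference by itself. The count of calls depended on which library was left out. Without ethanol 2 edgeR called 201 genes higher and 10 lower. Without control 1 it called 1 higher, the gene model Gm9855, named here after its value was seen, which had 13.9 CPM in control 1 and 0 in control 2 and control 3. DESeq2 called 3 higher and 3 lower without ethanol 1, and 1168 and 698 without ethanol 2. In counts simulated at this spread, with genes drawn independently, edgeR recovered 40.9% of genes changed 2-fold and 2.5% of those changed 1.5-fold. In such counts most smaller changes would be missed in single genes.

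Among the gene lists fixed before the data were examined, markers of D2 medium spiny neurons stood higher in ethanol. These neurons form the indirect output pathway of the striatum. The list was called higher by camera (adjusted p = 0.00193, adjusted p = 0.624 with an estimated correlation), with a median log2 fold change of 0.63 and 7 of 8 members higher. Over all genes 0 of the 8 members passed, and 2 passed adjusted over the list alone. They were Drd2, the dopamine D2 receptor gene, at 23.2 ± 2.18 CPM in control and 42.1 ± 11.2 CPM in ethanol (SD, n = 3 each), and Gpr6, at 10.4 ± 0.72 and 17.8 ± 5.33 CPM, with a log2 fold change of 0.77 that was 0.50 without ethanol 2. Adora2a, an adenosine receptor gene of the same neurons, had a log2 fold change of 0.59, which was 0.20 without ethanol 2 and 0.35 with limma-voom sample weights. In the list's mean log2 CPM, all 3 ethanol libraries lay above all 3 control libraries. The same held for other lists, among them the dorsal striatum and opioid lists, which were not called. The call held in each fit that left out 1 library. Markers of D1 medium spiny neurons were not called, with a median of 0.06, 5 of 9 members higher, and Drd1 at a log2 fold change of 0.51 (SE 0.20).

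Genes shared by both kinds of medium spiny neuron were also called higher (adjusted p = 0.00193, adjusted p = 0.624 with an estimated correlation), with 17 of 19 members higher and a median of 0.26. Over all genes 0 members passed, and 2 passed adjusted over the list alone, namely Adcy5, the main adenylyl cyclase of the striatum, with a log2 fold change of 0.72 (SE 0.18), and the sodium channel subunit gene Scn4b, with 0.73 (SE 0.18). Without ethanol 2 the median was 0.07 and the call was lost (adjusted p = 0.231). Markers of the septum and basal forebrain were called higher (adjusted p = 0.0311, adjusted p = 0.624 with an estimated correlation), with 10 of 12 members higher and a median of 0.34. None of its members passed over all genes or adjusted over the list alone, and Gbx1 and Trpc4 led it with log2 fold changes of 1.13 and 0.59, the latter 0.33 without ethanol 3. Its call was lost without control 2 (median 0.31, adjusted p = 0.0542) and without ethanol 3 (median 0.23, adjusted p = 0.24). Markers of cortical glutamatergic neurons were called lower (adjusted p = 0.00966, adjusted p = 0.624 with an estimated correlation), with 10 of 12 members lower and a median of -0.56. None of them passed over all genes or adjusted over the list alone. The vesicular glutamate transporter gene Slc17a7 was at 289, 58.2 and 102 CPM in the control libraries and 24.7, 9.42 and 55.9 CPM in the ethanol libraries. Its log2 fold change of -2.32 became -1.42 without control 1, and the list's call was lost without control 1 (median -0.38, adjusted p = 0.126) and without ethanol 2 (median -0.42, adjusted p = 0.339).

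**Figure D2:**
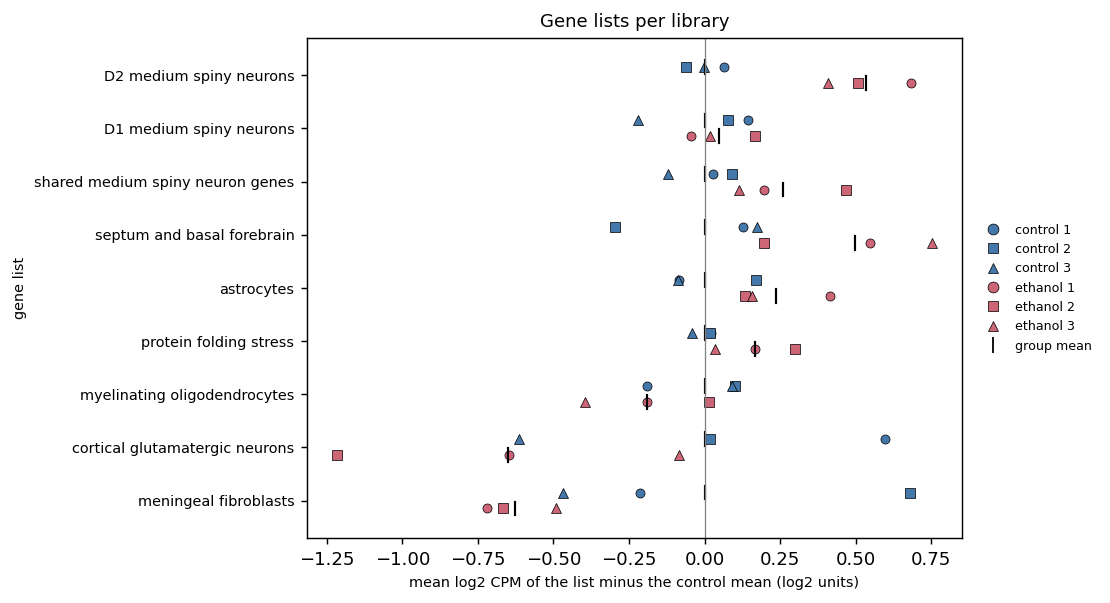
Mean log2 CPM of the members of 9 gene lists, minus the mean of the control libraries. Each point is 1 library and the black bars are group means. The 3 ethanol libraries lie above all control libraries for D2 medium spiny neurons, shared medium spiny neuron genes, septum and basal forebrain, and protein folding stress. They lie below all control libraries for meningeal fibroblasts. The libraries of both groups overlap for the other lists, D1 medium spiny neurons included.

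Of the glial lists, astrocyte markers were called higher (adjusted p = 0.00994, adjusted p = 0.624 with an estimated correlation), with 12 of 14 members higher and a median of 0.25. Over all genes 0 passed and adjusted over the list alone 1 passed, the glutamate transporter gene Slc1a3, at 291 ± 31.3 CPM in control and 483 ± 78.7 CPM in ethanol (SD, n = 3 each). Mlc1 had a log2 fold change of 0.51. The astrocyte call was lost without control 1 (median 0.22, adjusted p = 0.0675) and without control 3 (median 0.19, adjusted p = 0.0594), and the median was 0.14 without ethanol 1 and 0.16 with total counts only. Markers of myelinating oligodendrocytes were called lower (adjusted p = 0.0341, adjusted p = 0.647 with an estimated correlation), with 12 of 18 members lower and a median of -0.10. Over all genes 0 passed and adjusted over the list alone 1 passed, Hapln2, a link protein of the nodes of Ranvier, at 126 ± 12.3 and 77.4 ± 2.99 CPM. Ermn had a log2 fold change of -0.64, which was -0.29 with GC and length trends removed, and Mbp, the myelin basic protein gene, had -0.08. The oligodendrocyte call was lost without control 2 (median -0.07, adjusted p = 0.204), control 3 (median -0.04, adjusted p = 0.148) or ethanol 3 (adjusted p = 0.765), and its median lay between -0.22 without ethanol 2 and 0.03 without ethanol 3. Oligodendrocyte precursors (median -0.0084) and microglia (0.25, 15 of 18 members higher) were not called. Microglia were called higher with GC and length trends removed, and in the fits without control 2, ethanol 1 or ethanol 3.

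Markers of meningeal fibroblasts were called lower (adjusted p = 0.00193, adjusted p = 0.624 with an estimated correlation), with 11 of 11 members lower and a median of -0.57. Over all genes 0 passed and adjusted over the list alone 1 passed, the sulfate transporter gene Slc13a4, at 3.02 ± 0.87 CPM in control and 1.008 ± 0.14 CPM in ethanol (SD, n = 3 each). Without control 2 the median was -0.18 and the call was lost (adjusted p = 0.174), as it was with limma-voom sample weights (median -0.30, adjusted p = 0.0648). Choroid plexus and ependyma were not called, with 8 of 13 members higher and a median of 0.10, and were called higher without control 3. Over all genes 0 members passed and adjusted over the list alone 2 passed, Ttr and Kcnj13, which were lower in ethanol. Ttr, a secreted carrier protein of the choroid plexus, stood at 394 CPM in control 3 and at 0.73 to 4.63 CPM in the other 5 libraries, and its log2 fold change of -6.76 was -1.46 without control 3. Kcnj13 had 0 reads in ethanol 2 and ethanol 3. Blood cells were not called, with 0 members passing over all genes and 1 adjusted over the list alone, Alas2, the first enzyme of haem synthesis in red cells, with a log2 fold change of 1.27. The beta-globin gene Hbb-bs was at 0 in control 2 and ethanol 3 and at 71.3 to 190 CPM in the other 4 libraries, and near-identical globin copies make that split uncertain. Its log2 fold change of 0.72, which was -0.38 without ethanol 2, is also the median of the 5 measured blood cell genes. Endothelial and mural cells had a median of 0.0024 and striatal interneurons one of 0.10, with Chat, the enzyme of acetylcholine synthesis, at 0.92, and neither list was called.

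The protein folding stress list, made of chaperones and genes of the unfolded protein response, was called higher (adjusted p = 0.0311, adjusted p = 0.624 with an estimated correlation), with 14 of 20 members higher and a median of 0.23. None passed over all genes or adjusted over the list alone, and Hspa5 and Hyou1, chaperones of the endoplasmic reticulum, had log2 fold changes of 0.49 (SE 0.15) and 0.57 (SE 0.18). The median was 0.06 without ethanol 2, where the call was lost (adjusted p = 0.444). The call was also lost without control 1 (median 0.26, adjusted p = 0.0652) or control 3 (median 0.21, adjusted p = 0.0686), and with limma-voom sample weights (median 0.12, adjusted p = 0.103). With total counts only the median was 0.14.

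The other lists were not called in this fit, though several of them were called in some of the alternative fits. Immediate early genes, which respond to neuronal activity, had a median of 0.04 with 13 of 22 members higher, where Egr3 had a log2 fold change of 0.79, Npas4 one of -0.87 and Fos one of -0.05. The plasticity factor list had a median of 0.09, and Bdnf a log2 fold change of -0.48 (SE 0.33), which lay between -0.74 without control 3 and -0.28 without ethanol 2, and was -0.28 with GC and length trends removed. Interferon response genes had 13 of 15 members lower, a median of -0.26 and an adjusted p of 0.0527 by camera, with Irf7 at -0.72. They were called lower with DESeq2, with limma-voom, with GC and length trends removed, and without control 1 or control 3. Innate immune signalling had a median of 0.05. Of the transmitter systems, medians were 0.08 for dopamine signalling, 0.26 for the opioid system, 0.18 for the endocannabinoid system, 0.21 for the GABA system, 0.25 for ionotropic glutamate receptors and 0.19 for metabotropic receptors with the postsynaptic scaffold. Adjusted over the list alone, 2 dopamine genes (Drd2 and Adcy5) and 1 opioid gene passed, the nociceptin receptor gene Oprl1 at 60.5 ± 2.50 CPM in control and 99.3 ± 20.2 CPM in ethanol (SD, n = 3 each), and over all genes 0 did. Slc32a1, the vesicular GABA transporter gene, had a log2 fold change of 0.72 and did not pass in either way. Stress and feeding peptide systems had a median of 0.08, with the oxytocin receptor gene Oxtr at 0.75, and glucocorticoid responsive genes one of 0.10.

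Ethanol and aldehyde metabolism had a median of 0.25 and ethanol-sensitive channels one of 0.22. Ethanol-sensitive channels, the GABA system and ionotropic glutamate receptors were each called higher with limma-voom sample weights, with trends removed and without ethanol 2. Medians were 0.24 for ventral striatum and shell, 0.15 for dorsal striatum, -0.04 for DNA methylation and histone modifiers and 0.13 for the circadian clock. They were 0.03 for cholesterol synthesis, 0.0098 for cytosolic ribosomal proteins and 0.0085 for the extracellular matrix. Nuclear-encoded oxidative phosphorylation had a median of -0.15 with 60 of 80 members lower and an adjusted p of 0.0527 by camera. It was called lower with total counts only, no low-count filter, limma-voom with or without sample weights and the replicate block. It was also called lower without control 1, control 2 or ethanol 2. Ribosomal proteins were called higher without ethanol 1, and lower with sample weights and without ethanol 2. In the dorsal striatum list Reln, an extracellular guidance protein gene, passed adjusted over the list alone with a log2 fold change of 0.99 (SE 0.24), as did Hapln2 in the matrix list, and over all genes 0 did. The sign of the median, the mean and the test differed in 6 lists that were not called, namely oligodendrocyte precursors, endothelial and mural cells, choroid plexus and ependyma, innate immune signalling, the extracellular matrix and ribosomal proteins. Of the 37 lists tested, 5 were called higher and 3 lower by camera with a preset correlation of 0.01, and with an estimated correlation 0 were called. The test fry called 0 lists, whether for a shift 1 way (smallest adjusted p 0.206) or for change in either direction (0.16).

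All 6 libraries also held transcripts of neurons that lie outside the nucleus accumbens. These genes were looked at after the data had been seen. Hcrt, the orexin precursor of the lateral hypothalamus, stood at 312 ± 58.1 CPM in control and 325 ± 40.6 CPM in ethanol (SD, n = 3 each), a log2 fold change of 0.06 (SE 0.18). Pmch, the precursor of melanin-concentrating hormone from the same region, stood at 644 ± 106 and 322 ± 91.9 CPM, with a log2 fold change of -1.001 (SE 0.23) that did not pass in edgeR (adjusted p = 0.419) and did in DESeq2 (adjusted p = 0.0223). The dopamine transporter gene Slc6a3, transcribed in midbrain dopamine neurons, lay between 27.2 and 160 CPM and Th, the rate-limiting enzyme of dopamine synthesis, between 35.0 and 121 CPM. Both were lowest in ethanol 2. For comparison, Drd2 lay between 20.9 and 55.1 CPM. Of 7 genes on a thalamus list 4 exceeded 10 CPM in every library, among them Prkcd at 40.3 to 281 CPM and Tcf7l2 at 18.8 to 59.1 CPM. Of 5 hindbrain genes, 0 exceeded 10 CPM in any library, the highest being Tph2 at 1.64 CPM.

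**Figure D3:**
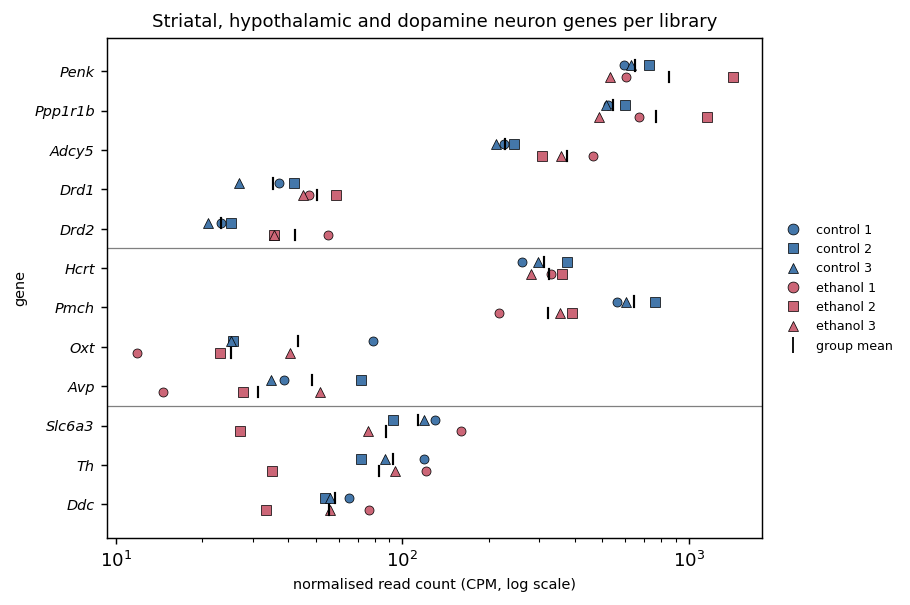
Normalised read count (CPM, log axis) of 5 striatal genes, 4 hypothalamic genes and 3 genes of dopamine neurons, from top to bottom. Each point is 1 library and the black bars are group means. Hcrt lies between 262 and 376 CPM in all 6 libraries, above Drd2 in each.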

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

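Removal of GC and length trends and the tests of single transcripts were chosen after the data had been seen, the other alternatives before. A log2 fold change of at least 0.5 was asked only of genes already past the threshold, so its count of 0 was fixed beforehand. limma-voom with and without sample weights called 0 genes. With edgeR, 0 were called in either direction under the other scalings and filters, the thinned counts and the trend removal. The same held for the single transcripts (1475 at an unadjusted p under 0.05) and at an adjusted p under 0.10. The exceptions were DESeq2, with 51 higher and 93 lower, and fits without 1 library, with 0 to 201 higher and 0 to 10 lower, the highest of both without ethanol 2, which shared 30 genes with the 144 of DESeq2. Without 1 library DESeq2 itself called from 3 higher and 3 lower (without ethanol 1) to 1168 and 698 (without ethanol 2). Genes at an unadjusted p under 0.05 were 838 higher and 843 lower, or 49.9% higher. They were 455 and 1064 (30% higher) with total counts only, 1337 higher with limma-voom sample weights, 1304 and 1291 with GC and length trends removed, and 277 to 2028 and 452 to 1621 without 1 library. The cause was not tested, except that such fits have fewer samples. Lists called higher numbered 5, against 8 with sample weights, 10 with trends removed, 8 at an adjusted p under 0.10 and 3 to 9 without 1 library. Lists called lower numbered 3, against 5 with limma-voom, 5 at an adjusted p under 0.10 and 2 to 4 without 1 library. With an estimated correlation and with fry both counts were 0. The median log2 fold change of all genes stayed between -0.06 and 0.03 in the scalings and filters. Of 52 named genes, 26 passed in DESeq2 and 9 without ethanol 2. Those that turned direction were Hbb-bs (0.72, -3.59 with sample weights, -0.38 to 1.37 without 1 library), Fos (-0.05, -0.32 to 0.11 without 1 library) and Mbp (-0.08, -0.165 to 0.0726), as did the median of myelinating oligodendrocytes (-0.10, -0.219 to 0.0319). Hbb-bs, Fos and Mbp passed in none of these fits. Apart from fits without 1 library, list calls were lost for septum and basal forebrain with a stricter filter (adjusted p = 0.055) and, with sample weights, for cortical neurons (0.14), meningeal fibroblasts (0.0648) and protein folding stress (0.103). Whether replicate numbers pair the samples is not stated in the labels. Deviations of same-numbered samples from their group means correlated at 0.146, -0.031 and -0.017. This cannot decide it, since deviations from the mean of a group of 3 cancel out within that group. With the replicate block edgeR called 0 higher and 0 lower genes (658 and 987 at an unadjusted p under 0.05) and 5 and 4 lists. Removal of mitochondrially encoded genes was not run, since the table used here held 0 of them. Depth limits statements on genes near 3 reads per library.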

Other observations

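The 3 gene groups in this paragraph, the region lists and the tests of explanations in this part were chosen after the data had been seen. The D2 list, the gene test and its count at an unadjusted p under 0.05 were fixed before. For called lists by split only the prediction was written before that test's own result was seen, and the bar for trend removal on the rival split was raised after its result was seen. No test of the 3 groups as such is given, since they were chosen after changes of some members had been seen, Col16a1, Pcdha3, Pcdha11 and most of the noncoding RNAs, Neat1 and Meg3 included, among them. Collagen chains stood lower in ethanol, with 38 of 43 measured genes lower, 20 of them at an unadjusted p under 0.05, and a median log2 fold change of -0.67. The median lay between -0.97 and -0.54 without any 1 library. Meningeal fibroblast markers, of which 3 are collagen chains, stood lower beside them in 11 of 11 cases with a median of -0.57. Long noncoding RNAs kept in the nucleus were lower in 9 of 10 cases, with a median of -1.07. Meg3, an imprinted RNA, stood at 2166 ± 558 CPM in control and 1042 ± 563 CPM in ethanol (SD, n = 3 each), Malat1 at 207 ± 58.3 and 145 ± 80.4 CPM, and Snhg14 went the other way with a log2 fold change of 1.28. Clustered protocadherins, cell adhesion genes of which some share exons, were higher in 52 of 57 cases with a median of 0.32, which was 0.20 without ethanol 1. Another split of the 6 samples into 3 and 3 gave protocadherins a larger median in size, 0.424. Other splits reached 0.648 for collagen chains and 0.924 for the noncoding RNAs, close to the real split. No gene of these groups passed in edgeR over all genes.

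For 5 of the 8 called lists another split of the samples gave a median of larger size than the real split. The size was 0.56 in the real split and at most 0.91 in the others for cortical glutamatergic neurons, 0.10 and 0.33 for myelinating oligodendrocytes, 0.34 and 0.44 for septum and basal forebrain, 0.23 and 0.26 for protein folding stress, and 0.265 and 0.305 for shared medium spiny neuron genes. The real split had the largest for D2 medium spiny neurons, for meningeal fibroblasts (0.57 and 0.51) and for astrocytes (0.25 and 0.235). Of the 10 splits, 7 called the meningeal list and 3 the astrocyte list. Being the largest of 10 cannot tell the real grouping from chance.

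Hypothalamic, midbrain and thalamic transcripts were present in all 6 libraries labelled nucleus accumbens core. Of 20 genes on lists for the hypothalamus and for dopamine neurons, 9 exceeded 10 CPM in every library, as did 4 of 7 on a thalamus list, against 0 of 5 hindbrain genes, so tissue from outside the nucleus accumbens, the hypothalamus and ventral midbrain included, is a candidate source. Reads counted for Parpbp, which overlaps Pmch, came to at most 0.26% of the Pmch level. This alone cannot exclude Parpbp as a source, since reads of overlapping genes may be divided wrongly in these estimated counts. Reads carried over from 1 other library would keep Pmch and Hcrt in 1 ratio, but that ratio differed 3.27 times between the libraries, from 0.657 in ethanol 1 to 2.15 in control 1. Carry-over from several libraries, wrongly divided Parpbp reads, the dissection, and a change of Pmch itself with ethanol stayed open. No test of the animals' state was made.

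The number of genes at an unadjusted p under 0.05 was 1681 for the real split of the samples and 1943 for the split of control 1, ethanol 1 and ethanol 3 against the others (the rival split), so 2 of the 10 splits gave as many, and 10 splits are too few for a share under 0.05. For DESeq2 the real split gave 144 genes and the highest other 234 (2 of 10 splits as large), for edgeR's calls all 10 splits gave 0, and for called lists the real split gave 8 and the highest other 14 (8 of 10 as large). With trends over GC content and transcript length removed per library the rival split gave 1297 genes, a fall of under 1.5 times to a count still above the 789 met with no difference, so these trends and other causes of that split cannot be told apart, while across genes the deviation of a library followed length with a Spearman rank correlation from -0.575 in ethanol 2 to 0.498 in ethanol 3. The trends do not account for the real split as a whole, which gave 2595 genes with them removed, where the highest other split gave 1670 after 737 before (1 of 10 as large), so a rise was not particular to the real split. The ethanol exposure and unnamed differences in dissection stayed open.

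D2 medium spiny neuron markers stood higher in ethanol, with a median of 0.63, where the highest of the 9 other splits had 0.55 and 3 of the 10 splits called the list. A larger share of striatal tissue as the whole cause would raise D1 and D2 markers alike if no other tissue carried them. The D2 minus D1 difference in mean log2 CPM was 0.487 larger in ethanol (SE 0.164, exact permutation p = 0.1, two-sided, the smallest possible for 3 against 3). This cannot decide the question, since tissue from elsewhere may be present and its share of these markers was not measured. A larger share may account for some of the D2 rise, and how much cannot be told. Genes shared by both neuron types were higher in 17 of 19 cases with a median of 0.26 (up to 0.305 in size in the other splits). Drd1 had a log2 fold change of 0.51 with no overlap between groups. The D1 list as a whole had a median of only 0.06 with 5 of 9 members higher, and was not called. GC and length trends do not account for the D2 rise, since the median was 0.597 with the trends removed and the list was still called. A different part of the striatum in the tissue stayed open, with the lists for ventral striatum and shell (median 0.24, adjusted p = 0.231) and dorsal striatum (median 0.15, adjusted p = 0.195) not called, as did a change in D2 neurons with ethanol, which was not tested.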
